A study of Mus musculus with 6 samples.

How the data were processed

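RNA sequencing was run on 6 primary cancer cell lines grown from mouse pancreatic tumours, 3 of the genotype KPPC and 3 of the genotype PPSSC. Per the labels' protocols, tumours were minced, digested with collagenase IV and dispase II, stained with a viability dye and cultured in medium with serum, and total RNA was sequenced in paired-end mode on an Illumina HiSeq instrument. The labels do not say that lines with different replicate numbers came from separate mice. The p-values therefore measure only the spread between these 6 samples, which need not be the spread between mice.

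The authors deposited 1 table of RPKM values (reads scaled to gene length and to the size of the library), with 25641 genes named by symbol and 1 column per line. The submitters' processing notes name HISAT2 and DESeq2 and the genome builds GRCm39 and mm39. They give neither versions, nor roles, nor an order. The read counter, the gene annotation and any filter are not given in the sources used here. Each gene in the deposited table was above 0 in at least 1 library.

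Within a gene, the deposited RPKM values of the 6 libraries were whole multiples of 1 step after each library was multiplied by its own factor. From these steps the divisor of each library and the smallest whole read numbers of each gene were recovered, with implied gene lengths up to 130000 bases and a tolerance of 0.005 reads (2e-08 of the value for large read numbers). Whole reads were recovered for 25641 of 25641 genes. Any multiple of these numbers would give the same RPKM, so for genes with few reads, or reads in few libraries, they are lower limits. The implied lengths had no relation to annotated lengths: Spearman's rho across 7394 genes, which are not independent replicates, was 0.0199, and 0 of 9 mitochondrial genes lay within 1.1 times their annotated length. For mt-Co1 the implied length was 1959 bases and the annotated length 1545 bases. RPKM levels are therefore given for comparison between libraries within a gene. The filter on low values, the pseudocount and the rule for named genes still act on the RPKM itself, so which genes were tested and named, and the size of a log2(RPKM + 1) fold change set against that of another gene, depend on these lengths. In tests on simulated RPKM of 7481 genes the reads of 89.5% of genes were recovered exactly, and of 99.4% of genes with 10 or more reads in each library.

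The recovered reads summed to 23297254, 24047597 and 27286293 in the KPPC libraries 1, 2 and 3 and to 24699612, 27458203 and 27705729 in the PPSSC libraries. A read here may be a read pair. The library divisors of the deposited RPKM were 0.862 to 1.18 times these sums, so the deposited values carry a scaling between libraries beyond total reads, whose method is not given in the sources used here. No 2 replicates were the same library: chi-square per gene between replicates of a group lay between 128 and 298.

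Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), for genes with an RPKM of at least 1 in 3 or more of the 6 libraries (11351 genes). The linear model held the genotype alone, with empirical Bayes moderation using a mean-variance trend and robust estimation. Tests were two-sided and adjusted by Benjamini-Hochberg at 0.05. Fold changes are PPSSC minus KPPC on the log2(RPKM + 1) scale, which understates the change of genes with low values. Means are given with SD over 3 lines. Counts and recovered reads were not the main unit, so no count model was used for the main result.

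The 40 gene lists, the tests, the rule for the genes named and most of the alternatives were written before the data were examined, from textbook knowledge of pancreatic cancer. Of the lists, 32 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 32 lists. The rule named Kras, Trp53, Smad4 and Pdx1 whatever their change. It also named the 10 largest changes in each direction among genes past the threshold whose groups did not overlap and whose higher group had a mean RPKM of at least 5, leaving out predicted genes, pseudogenes and sex-linked genes. From each list it took up to 2 members per direction among those past the threshold, and otherwise the member with the smallest p, given as not passing. Other genes are named where a list or pattern is described, and these were chosen after their values were seen. Lists were also tested for an excess of called genes with a one-sided Fisher's exact test, adjusted over 64 tests, and that test was chosen after the data were seen.

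On simulated reads for 11351 genes (11209 of them past the filter) the limma test of PPSSC against KPPC recovered 13% of genes changed by a log2 fold of 1 and 95% of those changed by 2, and 5.26% of its calls were unchanged genes. A moderate change that missed the threshold is therefore not shown to be absent. The simulation changed a small set of well-covered genes and used 1 dispersion (0.0939) for all genes. Its rates need not hold in the real data, where more genes were called, or for genes with few reads.

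Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the variance model, library weights, a block for the replicate number, other list tests and leaving out each library in turn. Added after the data were seen were limma voom on the recovered reads (genes with 10 or more reads in 3 or more libraries), scaling to total recovered reads and the Fisher's exact test of lists. Tests outside limma used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9. The reference annotation at hand belongs to another build than the one in the submitters' processing notes, so it served for gene names, annotated lengths and the order of neighbouring genes, and no coordinates are given. Alleles, exons and sequence variants were not analysed here.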

Results

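Gene expression was measured in 6 mouse pancreatic cancer cell lines by RNA sequencing. The 3 KPPC lines came from tumours of mice with a Cre-activated mutant Kras allele and floxed Trp53, recombined by Cre under the Pdx1 promoter, a promoter active in the pancreatic epithelium. The 3 PPSSC lines came from tumours of mice with floxed Trp53 and floxed Smad4 under the same Cre and with no engineered Kras allele. Smad4 carries TGF-beta and BMP signals to the nucleus, Trp53 encodes the p53 tumour suppressor and Kras a GTPase that drives the MAPK cascade. The comparison asks how tumour cells that arose without an engineered Kras mutation differ from those with one. The groups differed at Kras and at Smad4 together, so the contrast cannot separate these loci. Recovered reads ranged from 23297254 to 27705729 per library, and the precision of each value is set mainly by the spread between the 3 lines of a group. Of the 25641 genes in the table, 8121, 7699 and 8304 were listed at 0 in the KPPC lines and 5762, 5106 and 5367 in the PPSSC lines.

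The gene deleted in PPSSC alone was lower there, and the other engineered loci did not pass the test. Smad4 was at 28.5 ± 0.912 RPKM in KPPC and 8.76 ± 2.16 RPKM in PPSSC (SD, n = 3 lines each), a log2 fold change of -1.62 (SE 0.28, limma adjusted p = 0.00564). The recovered reads over Smad4 were 1258, 1490 and 1847 in the KPPC lines and 341, 686 and 769 in the PPSSC lines. The labels do not say which exons are flanked by loxP sites, and the value of the whole gene includes exons that remain. Trp53, floxed in both groups, had 208, 223 and 486 reads in KPPC and 214, 318 and 326 in PPSSC, with a log2 fold change of -0.21 (SE 0.25, limma adjusted p = 0.637).

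Kras, from both alleles together, was at 111 ± 68.7 RPKM in KPPC and 154 ± 54.9 RPKM in PPSSC. Its log2 fold change was 0.57 (SE 0.44, limma adjusted p = 0.456). The level varied within each group: the KPPC lines 1, 2 and 3 had 71.1, 71.5 and 190 RPKM and the PPSSC lines 101, 211 and 152 RPKM. Pdx1, a transcription factor of pancreatic progenitors whose promoter drove Cre, was at 74.2 ± 27.2 RPKM in KPPC and 21.4 ± 23.2 RPKM in PPSSC. Its log2 fold change was -2.22 (SE 0.70, limma adjusted p = 0.0795), with line 3 of PPSSC at 48.0 RPKM against 4.76 and 11.6 RPKM in the others. Pdx1 passed without that line and with estimated library weights, and adjusted over the list alone Smad4 and Pdx1 were lower.

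**Figure D1:**
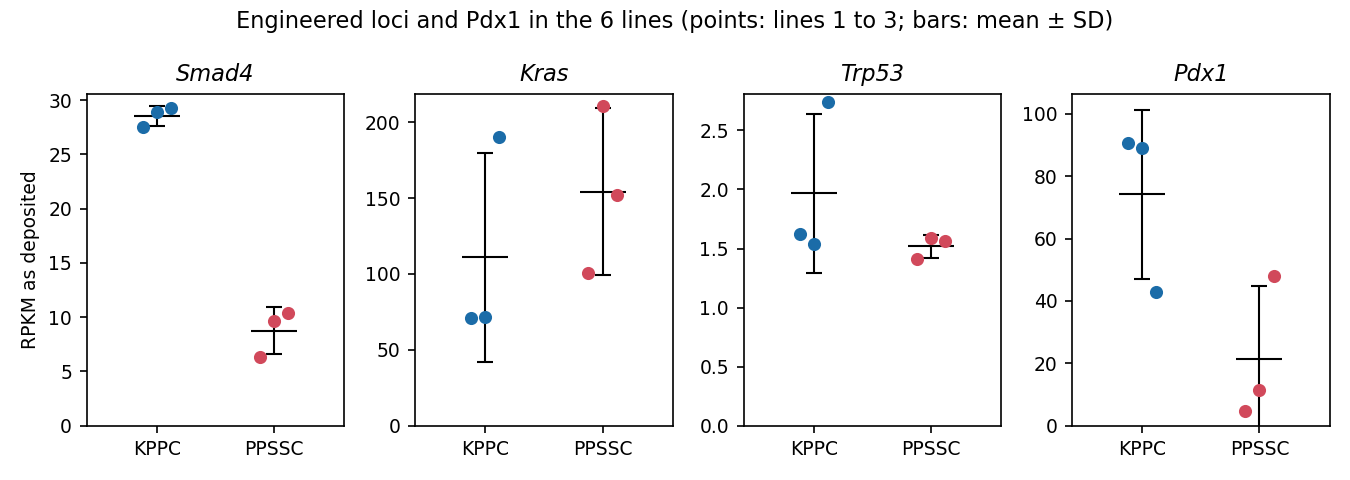
RPKM of Smad4, Kras, Trp53 and Pdx1 in each line (points, lines 1 to 3 from left to right; linear axes from 0), with mean and SD of the 3 lines per group as bars. Smad4 lies between 27.5 and 29.2 RPKM in KPPC and between 6.30 and 10.4 RPKM in PPSSC, whereas the groups overlap for Kras, Trp53 and Pdx1.

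Across the transcriptome 825 genes were higher and 613 lower in PPSSC with limma, and the lists with most genes higher were epithelial identity, chemokines and cytokines, and basal-like subtype. The rule took genes by their log2(RPKM + 1) fold change, which depends on the level and so on gene lengths that could not be verified, so their order is not a ranking of change. Among those that rose in PPSSC was St14, the membrane protease matriptase, at 1.76 ± 2.27 RPKM in KPPC and 1663 ± 460 RPKM in PPSSC (limma log2 fold change 9.54, SE 0.55, adjusted p = 3.05e-05). Others were Ppbp, a platelet chemokine (8.41), Ceacam1, a cell adhesion molecule (7.76), and Gpx2, an epithelial glutathione peroxidase (7.61). Sfn (14-3-3 sigma, 7.39), Cldn4 (a claudin, 7.34), Cbr2 (carbonyl reductase, 7.14), Ly6d (a surface marker of squamous epithelium, 7.09) and Ap1m2 (an epithelial clathrin adaptor subunit, 7.04) rose too. Klra4, a lectin-like receptor of natural killer cells, was listed at 0 in all 3 KPPC lines and had 307, 161 and 109 RPKM in the PPSSC lines (limma adjusted p = 1.63e-05). Klra4 and Ceacam1 have close paralogs, between which the authors' counting could split reads.

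Among the genes that fell in PPSSC were Cldn18, a claudin of stomach and lung, with a limma log2 fold change of -7.27, and Cdh17, the liver-intestine cadherin (-5.16). Cldn18 was at 181 ± 46.0 RPKM in KPPC and 0.169 ± 0.224 RPKM in PPSSC (SE 0.30, adjusted p = 1.07e-05). Nkx2-3, a homeobox factor of gut and spleen, was at 140 ± 54.9 RPKM in KPPC and listed at 0 in all 3 PPSSC lines (limma adjusted p = 1.63e-05). The muscle enolase Eno3 (-5.06), the RNA-binding protein Igf2bp3 (-5.01), the hedgehog ligand gene Dhh, the transcription factor Gata2 (-4.97), the myosin gene Myo15b (-4.96) and the intermediate filament gene Vim (-4.78) also fell. Tpm3-rs7 (-4.86) is nearly identical in sequence to Tpm3, so its reads are uncertain. Myo15b did not pass without KPPC line 1 or KPPC line 2, and neither Myo15b nor Vim passed without a filter on low values. Ppbp had 57.0 RPKM in line 3 of PPSSC against 1920 and 869 RPKM in lines 1 and 2.

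These 825 higher and 613 lower genes were those of 11351 tested with limma that had a Benjamini-Hochberg adjusted p under 0.05. For all 1438 of them the values of the groups did not overlap. Over all tested genes the share without overlap was 31.5%, against the 10% that chance gives for 3 against 3. The first principal component, with 60.9% of the variance, separated the groups, and correlations of log2 values were 0.932 to 0.969 within groups and 0.844 to 0.889 between them. Scaled to total recovered reads instead of the authors' divisors, the split was 937 higher and 403 lower (69.9% higher against 57.4%), since that scaling shifts the median log2 fold change of all genes from -0.00429 to 0.18. The counts changed as well when 1 line was left out, which also lowers the power. They were 577 higher and 261 lower without KPPC line 2, 526 and 247 without PPSSC line 2, and 706 and 359 without PPSSC line 1. Without KPPC line 1 they were 638 and 405, without PPSSC line 3 764 and 631, and without KPPC line 3 886 and 715. With estimated library weights 1245 were higher and 1054 lower. Without a filter on low values, which put all 25641 genes into the adjustment, 611 were higher and 231 lower, and 52 of the 135 genes named here or in the closing section that had passed did not pass. Of the 45 among them with an adjusted p over 0.01 none passed without that filter.

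Epcam, Esrp1 and Cldn7 were close to 0 in KPPC and expressed in PPSSC, while E-cadherin, simple keratins and Cldn3 (74.5 ± 51.0 RPKM in KPPC) were expressed in both. Of 27 tested genes of epithelial identity, 18 rose and none fell (19 higher and 2 lower adjusted over the list alone). Epcam, an epithelial adhesion molecule, was at 0.198 ± 0.0315 RPKM in KPPC and 105 ± 21.8 RPKM in PPSSC (limma log2 fold change 6.44, SE 0.27, adjusted p = 1.07e-05). The splicing regulator Esrp1 rose from 0.101 ± 0.0879 to 94.3 ± 7.67 RPKM (6.44, SE 0.25, limma adjusted p = 1.07e-05), and the tight-junction gene Cldn7 from 0.264 ± 0.234 to 142 ± 39.7 RPKM (6.81, SE 0.30). The transcription factors Ehf and Grhl2 and the junction genes Cldn3 and Ocln rose with them. Cdh1, which encodes E-cadherin, was at 290 ± 88.5 RPKM in KPPC and 332 ± 80.0 RPKM in PPSSC (log2 fold change 0.21, SE 0.32, limma adjusted p = 0.723). Log2 fold changes of the simple keratins Krt8, Krt18 and Krt19 were -1.75, -1.43 and -1.09, with limma adjusted p of 0.0771, 0.0544 and 0.217. Without KPPC line 3, whose keratin values were the lowest of the KPPC lines, these 3 keratins fell in PPSSC, and Krt18 fell with quantile normalization and with voom on the recovered reads. The list passed with camera (adjusted p = 2.20e-14; adjusted p = 0.554 with an estimated correlation). It held more higher genes than the background by Fisher's exact test (one-sided adjusted p = 4.31e-13), which takes genes as independent.

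Tested mesenchymal genes went the other way. Of 16 tested members, 6 fell in PPSSC (6 adjusted over the list alone) and none rose. The list has 26 members, and those under the RPKM filter were not tested and did not all go this way. Of these, Fstl1, Loxl1, Mmp2 and Tagln were higher in every PPSSC line than in any KPPC line. The first 3 had most of their reads in PPSSC line 3 (2249, 1165 and 347). Zeb2 was lower in PPSSC lines 1 and 2 than in any KPPC line. Vim, which encodes vimentin, was at 1322 ± 600 RPKM in KPPC and 74.9 ± 87.4 RPKM in PPSSC (limma log2 fold change -4.78, SE 0.86, adjusted p = 0.00789). S100a4, a calcium-binding protein of motile cells, fell from 18.5 ± 10.6 to 1.54 ± 0.671 RPKM (-2.77, SE 0.49, limma adjusted p = 0.00725). The transcription factors Prrx1, Twist2 and Zeb1 and the N-cadherin gene Cdh2 also fell, Zeb1 and Cdh2 with limma adjusted p of 0.0453 and 0.0445. Among the fits that left out 1 line Zeb1, Cdh2 and Twist2 passed only without PPSSC line 3, and Prrx1 did not pass without KPPC line 2 or PPSSC line 2. Line 3 of PPSSC stood apart, with 174 RPKM of Vim against 11 and 39.2 RPKM in lines 1 and 2. It also held 19581 reads of the fibrillar collagen gene Col3a1 against 26 and 60, and 5203 reads of the chemokine gene Cxcl12 against 6 and 6. Without that line 13 of the 16 genes fell, and 2 did without KPPC line 2 or PPSSC line 2, 3 without each of the other lines and 3 after scaling to total reads, 4 with log2(RPKM + 0.1) or log2(RPKM + 0.5) and none without a filter on low values. Zeb1 and Cdh2 did not pass with either pseudocount, nor did these or Twist2 after scaling to total reads. The list passed with camera (adjusted p = 0.00021; adjusted p = 0.938 with an estimated correlation) and by one-sided Fisher's exact test (adjusted p = 0.00156).

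**Figure D2:**
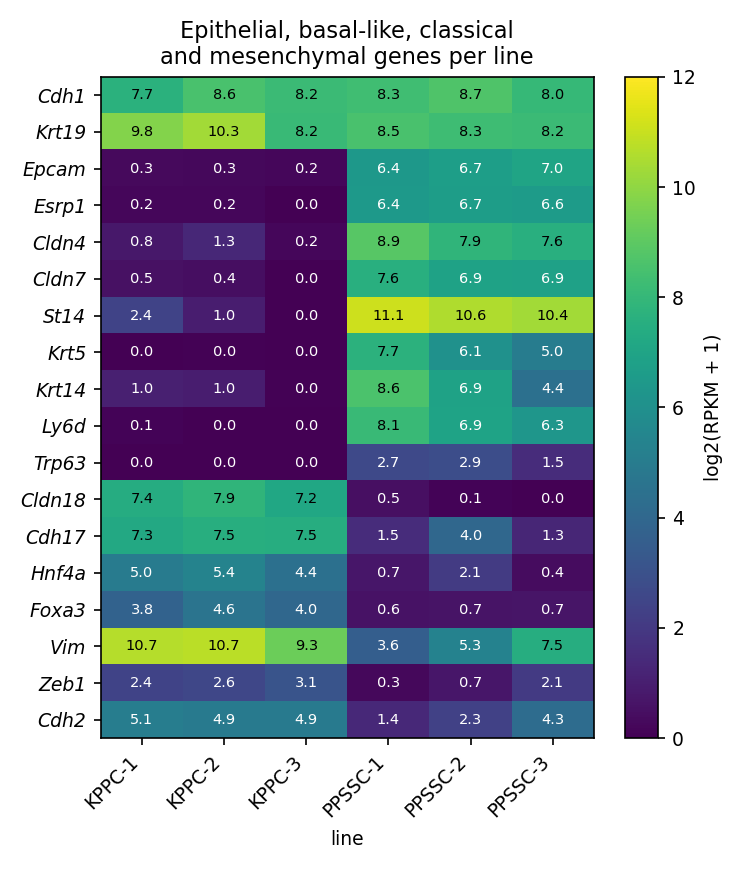
Heat map of log2(RPKM + 1) for 18 genes (from top to bottom) in the 6 lines (from left to right), with each value printed in its cell and a linear colour scale from 0 to 12. Cdh1 and Krt19 are expressed in all lines, Epcam to Trp63 are lower in KPPC, Cldn18 to Foxa3 are higher in KPPC, and the mesenchymal genes Vim, Zeb1 and Cdh2 are higher in PPSSC line 3 than in PPSSC lines 1 and 2.

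The lines also differed in genes that mark the classical and basal-like subtypes of pancreatic cancer. Of 18 classical genes, 10 fell in PPSSC and 1 rose (10 lower and 2 higher adjusted over the list alone). Besides Cldn18 and Cdh17, these included the endodermal transcription factor gene Hnf4a, at 30.4 ± 9.89 RPKM in KPPC and 1.41 ± 1.63 RPKM in PPSSC (limma log2 fold change -3.86, SE 0.47, adjusted p = 0.00114). Foxa2, Foxa3 and Hnf1a, factors of the same endodermal network, also fell, whereas the endodermal factor Foxa1 rose by 2.26 (limma adjusted p = 0.00233). The member that rose, Fam3d, a gut-secreted cytokine-like protein, was listed at 0 in all KPPC lines and at 33.0, 13.3 and 5.19 RPKM in PPSSC (limma adjusted p = 0.00214). Gata6, a regulator of the classical programme, was at a log2 fold change of -0.30 (SE 0.47, limma adjusted p = 0.737). The list passed with camera (adjusted p = 0.000159; adjusted p = 0.938 with an estimated correlation) and by one-sided Fisher's exact test (adjusted p = 1.85e-07), and 6 members fell without KPPC line 1, without KPPC line 2 or without a filter on low values. Without PPSSC line 3, 3 members rose, and 2 did after scaling to total reads.

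Of 19 basal-like genes, 9 rose in PPSSC and 1 fell (11 higher and 1 lower adjusted over the list alone). Krt5, a keratin of basal epithelial cells, was at 0.0111 ± 0.0193 RPKM in KPPC and 102 ± 92.9 RPKM in PPSSC (limma log2 fold change 6.26, SE 0.58, adjusted p = 0.000267). Krt14, the partner of Krt5, was at 0.688 ± 0.568 and 174 ± 187 RPKM (5.95, SE 0.89, limma adjusted p = 0.00316). The basal-cell transcription factor Trp63 was at 0.0036 ± 0.00623 and 4.49 ± 2.32 RPKM (2.34, SE 0.35, limma adjusted p = 0.0031), and Ly6d, Krt6a and Krt17 rose as well, Krt17 not without KPPC line 1, KPPC line 2 or PPSSC line 2. Dhrs9, a retinol dehydrogenase, fell (-0.77, SE 0.20, limma adjusted p = 0.0409), but did not pass without any 1 of the 6 lines, after scaling to total reads, without trend and robust estimation or without a filter on low values. Krt6a and Krt17 did not pass without that filter. Among the PPSSC lines, line 3 had the lowest values of Krt5 (31.6 RPKM against 207 and 66.9 in lines 1 and 2) and Krt14 (20.5 against 383 and 119). It was also the lowest PPSSC line for Krt6a, Krt17, Ly6d and Trp63. The list passed with camera (adjusted p = 0.000159; adjusted p = 0.938 with an estimated correlation) and by one-sided Fisher's exact test (adjusted p = 4.12e-05).

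Among 11 ductal and progenitor genes 1 rose and 1 fell (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.704). Muc1, a membrane mucin, rose from 6.24 ± 4.51 to 79.7 ± 19.6 RPKM (limma log2 fold change 3.67, SE 0.49, adjusted p = 0.00167), and Tspan8, a tetraspanin, fell (-1.27, SE 0.32, adjusted p = 0.0344), which among the fits that left out 1 line passed only without KPPC line 3. Tspan8 did not pass after scaling to total reads or without a filter on low values. Of 6 tested mucin and mucosal genes, 3 rose (3 adjusted over the list alone): Muc1, Muc4 (3.2, SE 0.34, limma adjusted p = 0.000602) and the siderophore-binding gene Lcn2. That list passed with camera (adjusted p = 0.0155; adjusted p = 0.938 with an estimated correlation). No member of the acinar list or of the endocrine list had the RPKM of 1 in 3 lines needed for testing. In single lines some were above it, such as Try5 at 20.0 RPKM in KPPC line 3 and Nr5a2 at 4.30 RPKM in PPSSC line 3.

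Genes downstream of RAS moved in both directions. Of 22 MAPK output genes, 4 rose in PPSSC, 1 fell and 17 did not pass (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.948; adjusted p = 4.99e-05 for change in either direction with fry). Fry for change in either direction passed 25 lists in all and does not compare a list with other genes, so that value is not particular to MAPK output. The phosphatase gene Dusp1 rose from 119 ± 16.5 to 712 ± 136 RPKM (limma log2 fold change 2.57, SE 0.27, adjusted p = 0.000498). The ETS factor Etv1 rose by 2.41 (SE 0.48, limma adjusted p = 0.0128), and the immediate early genes Fos and Ier3 rose too. Dusp6, the ERK phosphatase induced by ERK itself, fell from 116 ± 55.5 to 37.1 ± 6.85 RPKM (-1.53, SE 0.36, limma adjusted p = 0.0245). Without PPSSC line 2 only 1 member rose, 2 did without KPPC line 1, PPSSC line 1 or PPSSC line 3, and Dusp6 did not pass without KPPC line 2, PPSSC line 1 or PPSSC line 2, nor after scaling to total reads. Without a filter on low values 1 member rose and none fell.

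Receptor genes upstream of RAS differed one by one. Of 15 receptor tyrosine kinases, Kit, Egfr and Met rose and Tyro3 fell (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.398). Egfr, the epidermal growth factor receptor, was at 0.748 ± 0.0444 RPKM in KPPC and 4.44 ± 0.197 RPKM in PPSSC (limma log2 fold change 1.64, SE 0.22, adjusted p = 0.00191). Kit, the stem cell factor receptor, was at 0.027 ± 0.0043 and 4.58 ± 2.02 RPKM (2.37, SE 0.31, limma adjusted p = 0.00167), and Tyro3 fell by 1.30 on the log2 scale (SE 0.36, limma adjusted p = 0.0485). Only 2 receptor genes rose without KPPC line 2 or PPSSC line 2, and 2 fell without PPSSC line 3. Met did not pass without KPPC line 2 or PPSSC line 2. Of 6 EGF family ligands Nrg1 alone rose, by 1.41 (SE 0.33, limma adjusted p = 0.0248; 2 higher adjusted over the list alone; camera adjusted p = 0.837). Among 21 RAS family genes and regulators none rose, while the GTPase gene Rras (-1.24, SE 0.33, limma adjusted p = 0.0436) and the adaptor gene Shc1 (-1.10, SE 0.28, limma adjusted p = 0.0327) fell. Adjusted over the list alone 0 of these RAS genes passed, and camera, with an adjusted p of 0.916, pointed upward. Among the fits that left out 1 line, Tyro3 and Shc1 passed only without KPPC line 3, Rras only without PPSSC line 3, and Nrg1 only without KPPC line 3 or PPSSC line 3. Tyro3, Rras and Shc1 did not pass after scaling to total reads, nor Tyro3 with log2(RPKM + 0.1) or median ratio scaling, nor Rras with quantile normalization. None of Tyro3, Rras, Shc1, Nrg1 and Met passed without a filter on low values.

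**Figure D3:**
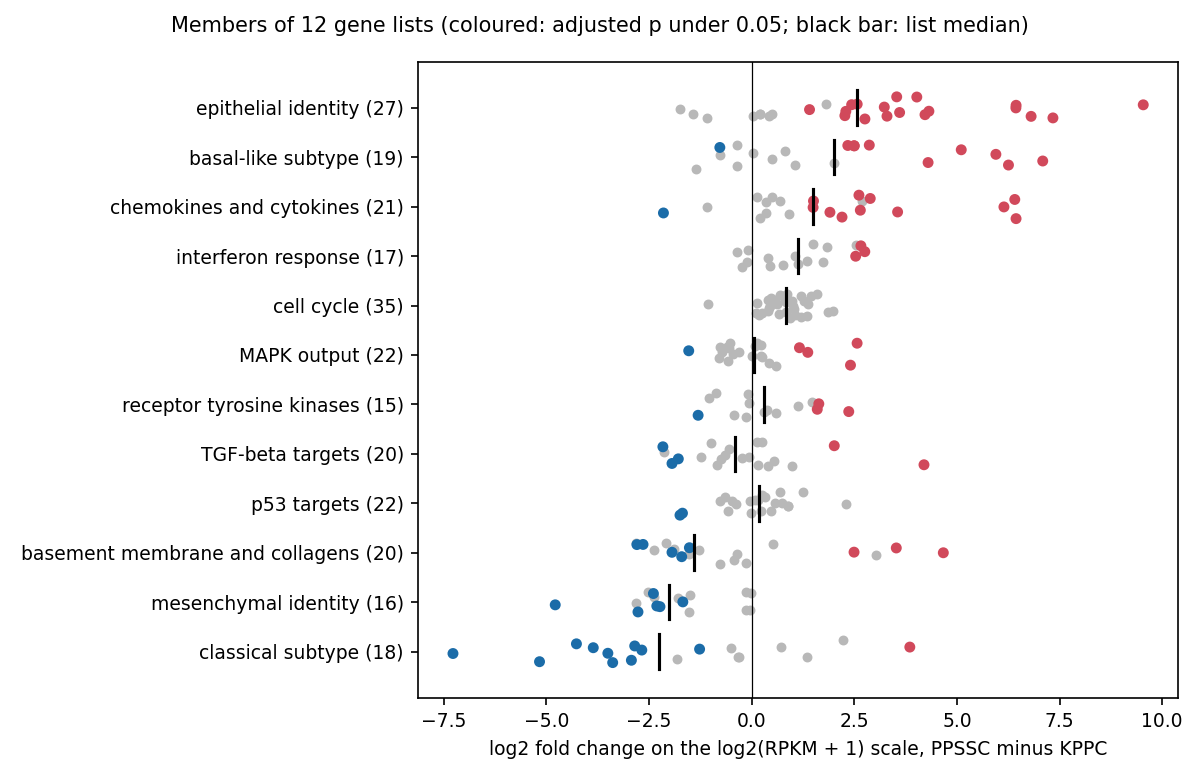
Limma log2 fold change on the log2(RPKM + 1) scale, PPSSC minus KPPC, of the tested members (points; number in brackets) of 12 lists, with vertical jitter only for legibility. Red points were higher and blue points lower in PPSSC at adjusted p under 0.05, grey points did not pass, and black bars are list medians. In the epithelial list 18 of 27 points are red, and in the classical list 10 of 18 are blue.

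Of 20 targets of TGF-beta, members moved in both directions in PPSSC: 2 rose and 3 fell (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.332). Thbs1, a matrix glycoprotein that activates TGF-beta, rose from 1.04 ± 0.552 to 41.4 ± 26.1 RPKM (limma log2 fold change 4.20, SE 0.50, adjusted p = 0.000984), and the integrin subunit gene Itgb6 rose by 2.01 (SE 0.28, limma adjusted p = 0.00196). The cell cycle inhibitor gene Cdkn2b (-2.16, SE 0.36, limma adjusted p = 0.00532), the collagen gene Col4a1 (-1.94, SE 0.38, limma adjusted p = 0.0108) and Ltbp3, which stores latent TGF-beta, fell. Without PPSSC line 2 only Cdkn2b of these fell, and Ltbp3 did not pass without KPPC line 1, KPPC line 2 or PPSSC line 1 either, nor after scaling to total reads. Without a filter on low values only Cdkn2b of these fell. Of 8 BMP targets Id2 rose by 2.47 (SE 0.46, limma adjusted p = 0.00932) and Id3 was lower at -3.23 (SE 0.42, limma adjusted p = 0.00149), with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.395). Id2 did not pass without PPSSC line 2 or without a filter on low values, and 3 BMP targets fell without KPPC line 3 and 2 without PPSSC line 3.

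Of 22 p53 targets none rose and 2 fell, Phlda3 (-1.74, SE 0.38, limma adjusted p = 0.0187) and the death receptor gene Tnfrsf10b (-1.68, SE 0.28, limma adjusted p = 0.00481). Adjusted over the list alone 2 fell, camera gave an adjusted p of 0.916, and 1 fell without KPPC line 1, KPPC line 2, PPSSC line 2 or a filter on low values, while 1 other rose without KPPC line 3 or PPSSC line 3 and 1 rose after scaling to total reads. Of 9 cell cycle inhibitor and senescence genes, Cdkn2a and Cdkn2b fell (2 lower adjusted over the list alone; camera adjusted p = 0.965), Cdkn2a from 75.1 ± 8.49 to 22.1 ± 12.4 RPKM (-1.84, SE 0.37, limma adjusted p = 0.0129), and 1 of the 2 passed without KPPC line 2, PPSSC line 2 or a filter on low values. Without KPPC line 1 or KPPC line 3, 1 gene of that list rose. None of 35 cell cycle genes and none of 32 DNA repair genes passed with limma, over all genes or adjusted over the list alone, while 4 and 8 had an unadjusted p under 0.05. With voom on the recovered reads none passed either, with library weights 1 cell cycle gene fell, 4 DNA repair genes rose and 1 fell, and after scaling to total reads 2 DNA repair genes rose. E2f2 had the smallest p in the former list (-1.06, SE 0.36, adjusted p = 0.101) and Blm, a DNA helicase, in the latter (1.6, SE 0.46, adjusted p = 0.0587). In camera both lists passed upward, with adjusted p of 0.0154 and 0.0329 (adjusted p = 0.961 with an estimated correlation for each). The cell cycle list turned downward without KPPC line 3 (camera adjusted p = 0.770), where 1 gene fell, and 3 of its genes rose without KPPC line 1. Of the DNA repair genes 2 rose without KPPC line 1, and 1 rose and 1 fell without KPPC line 3.

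Of 21 chemokines and cytokines, 11 rose and 1 fell in PPSSC (12 higher and 2 lower adjusted over the list alone). The neutrophil-attracting chemokine Cxcl5 was at 14.1 ± 9.90 RPKM in KPPC and 1203 ± 581 RPKM in PPSSC (limma log2 fold change 6.41, SE 0.51, adjusted p = 0.000131). Its relative Cxcl3 was at 0.267 ± 0.299 and 118 ± 58.8 RPKM (6.44, SE 0.42, limma adjusted p = 5.23e-05), and Cxcl1 and Cxcl2 rose as well. The cytokine gene Il1a was at 0.0239 ± 0.0229 and 85.9 ± 52.6 RPKM (6.14, SE 0.52, limma adjusted p = 0.00017), Csf3 rose too, and Tnf was listed at 0 in all KPPC lines. Il34, a ligand of the macrophage receptor Csf1r, fell by 2.15 on the log2 scale (SE 0.33, limma adjusted p = 0.00369), and 3 members fell without PPSSC line 3. The members that rose numbered 7 without a filter on low values. Among the PPSSC lines, line 3 had the lowest values of Il1a (27.8 RPKM against 130 and 99.5 in lines 1 and 2) and Csf3 (3.66 against 25.4 and 13.6). It was also the lowest PPSSC line for Cxcl1, Cxcl2, Cxcl3, Cxcl5 and Tnf. The list passed with camera (adjusted p = 6.38e-06; adjusted p = 0.164 with an estimated correlation) and by one-sided Fisher's exact test (adjusted p = 1.07e-06).

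Of 17 interferon response genes, Rsad2 (2.76, SE 0.48, limma adjusted p = 0.00634), Tlr3 (2.66, SE 0.35, limma adjusted p = 0.0016) and Usp18 rose and none fell (7 higher adjusted over the list alone). The list passed with camera (adjusted p = 0.00263; adjusted p = 0.938 with an estimated correlation). Line 3 of PPSSC carried the highest values of several members: Oas2 was at 18.4 RPKM there against 0.182 and 1.80 RPKM in lines 1 and 2, and Rsad2 at 18.5 against 4.08 and 5.22 RPKM. Without that line, or without PPSSC line 1, 5 members rose, and Rsad2 did not pass without a filter on low values. In class I antigen presentation, Erap1, a peptidase that trims peptides, was the 1 gene of 11 that rose (1.59, SE 0.26, limma adjusted p = 0.00454; 1 adjusted over the list alone; camera adjusted p = 0.501). Of 9 immune checkpoint ligands Vtcn1, a B7 family member, rose from 0.0357 ± 0.0213 to 6.49 ± 0.395 RPKM (2.85, SE 0.22, limma adjusted p = 0.000106). That list had 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.588, upward, with a median log2 fold change of -0.06 and a mean of 0.28). Of the class I genes 2 rose without PPSSC line 1 and with voom, log2(RPKM + 0.1) or log2(RPKM + 0.5). Of the checkpoint ligands 2 rose without KPPC line 1 and after scaling to total reads, and 1 fell without PPSSC line 3 and with voom.

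Of 20 basement membrane and collagen genes 3 rose and 5 fell (3 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0533; one-sided Fisher's exact test for an excess of lower genes, adjusted p = 0.0379). Col8a1 (4.67, SE 0.34, limma adjusted p = 8.67e-05), Col17a1, a hemidesmosome component of keratinocytes (3.52, SE 0.57, limma adjusted p = 0.00457), and Lama3 rose. Col7a1 (-2.79, SE 0.35, limma adjusted p = 0.00122), Hspg2, which encodes perlecan (-2.64, SE 0.73, limma adjusted p = 0.0482), Col4a1, Col18a1 and Lamc1 fell. In line 3 of PPSSC Hspg2 was at 69.5 RPKM against 5.99 and 12.4 RPKM in lines 1 and 2, and it passed only without that line among the fits that left out 1 line. With another pseudocount, filter or scaling Hspg2 did not pass. Lama3 did not pass without KPPC line 1, KPPC line 2, PPSSC line 1 or PPSSC line 2, nor with quantile normalization. The count of lower genes was 10 without that line, 2 without PPSSC line 2, 3 without KPPC line 2 or PPSSC line 1, 3 after scaling to total reads and 2 without a filter on low values. Of 14 matrix proteases and inhibitors 4 rose and 1 fell (4 higher and 1 lower adjusted over the list alone). Camera pointed upward (adjusted p = 0.916), as did the mean log2 fold change of 0.13, whereas the median was -0.53. The plasminogen activator genes Plat (2.91, SE 0.39, limma adjusted p = 0.00166) and Plau (2.76, SE 0.40, limma adjusted p = 0.00272) rose, and the inhibitor gene Timp2 fell by 1.08 on the log2 scale (SE 0.26, limma adjusted p = 0.0266). Among the fits that left out 1 line Timp2 passed only without KPPC line 3, and 2 genes of the list fell without KPPC line 3 or PPSSC line 3. Timp2 did not pass with quantile normalization, after scaling to total reads or without a filter on low values.

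Of 12 tested genes of the Wnt list, which holds ligands and antagonists besides targets, 3 rose (4 adjusted over the list alone). Camera gave an adjusted p of 0.0223, and of 0.938 with an estimated correlation. Wnt7b rose by 1.68 (SE 0.32, limma adjusted p = 0.0102) and the feedback inhibitor gene Axin2 rose as well. The secreted antagonist gene Sfrp1 was listed at 0 in the KPPC lines and at 8.19, 5.58 and 2.23 RPKM in PPSSC (limma adjusted p = 0.00264). Its recovered reads in PPSSC were 59, 53 and 22. Of 20 YAP/TEAD targets 3 rose (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.501), among them Rbms3 (3.01, SE 0.33, limma adjusted p = 0.000709) and Ccn1 (1.68, SE 0.46, limma adjusted p = 0.0457). Without KPPC line 1, PPSSC line 2 or PPSSC line 3 only 1 YAP/TEAD target rose, and Ccn1 passed only without KPPC line 3. Axin2 did not pass without KPPC line 1 or KPPC line 2. Without PPSSC line 3, 1 YAP/TEAD target and 1 gene of the Wnt list fell. Without a filter on low values 1 gene of each list rose, Ccn1 did not pass with log2(RPKM + 0.1), and 1 YAP/TEAD target fell with voom. None of 7 Notch genes passed, Notch1 being closest (-1.02, SE 0.35, limma adjusted p = 0.1; camera adjusted p = 0.916, downward, with a median of 0.03 and a mean of -0.08), while 1 had an unadjusted p under 0.05 and 0 passed with voom. Neither of the 2 tested hedgehog genes did, with Ptch1 at 0.23 (SE 0.29, limma adjusted p = 0.658).

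Metabolic and stress lists did not pass with camera. Of 24 glycolysis and hexosamine genes the hexokinase gene Hk2 (1.19, SE 0.31, limma adjusted p = 0.0409) and Rpia (0.98, SE 0.27, limma adjusted p = 0.0455) rose and the muscle phosphofructokinase gene Pfkm fell (-2.47, SE 0.40, limma adjusted p = 0.00433), with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.886). Neither Hk2 nor Rpia passed without KPPC line 1, without PPSSC line 1, without PPSSC line 2 or without PPSSC line 3, 1 passed without KPPC line 2 or KPPC line 3, and 4 genes of the list fell without KPPC line 3. Neither Hk2 nor Rpia passed without a filter on low values, nor Rpia with voom or with an RPKM minimum of 5. Of 16 hypoxia genes Adm alone rose (1.99, SE 0.51, limma adjusted p = 0.0358; 0 adjusted over the list alone; camera adjusted p = 0.282). Without KPPC line 2, 2 hypoxia genes rose, and without each other line none rose, while 1 fell without KPPC line 1. None rose with log2(RPKM + 0.1), without a filter on low values or with an RPKM minimum of 5. Of 21 cholesterol synthesis genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0793): Pcsk9 (-1.94, SE 0.36, limma adjusted p = 0.00876), the transcription factor gene Srebf2 (-0.96, SE 0.26, limma adjusted p = 0.0429) and Fdft1. Without each of the 6 lines in turn 1 of these genes fell, as after median ratio scaling, quantile normalization and scaling to total reads, and none fell without a filter on low values. None of 18 unfolded protein response genes passed with limma or voom (1 rose without KPPC line 3), and 2 had an unadjusted p under 0.05, with Xbp1 closest (-0.89, SE 0.28, limma adjusted p = 0.0732; camera adjusted p = 0.282).

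Of the lists for fibroblasts, leukocytes, endothelium, fat and nerve only the fibroblast list had enough tested members for a test as a group. The RPKM needed for testing rests on gene lengths that could not be verified, so a marker left untested need not be low: the endothelial marker Egfl7 had 168 to 441 reads in each line and was not tested. In line 3 of PPSSC the untested markers Dpt, Sox17 and Csf1r had 2077, 1101 and 163 reads. Of 5 tested fibroblast markers Pdpn, also a marker of basal keratinocytes, rose from 2.11 ± 2.02 to 30.5 ± 15.2 RPKM (limma log2 fold change 3.43, SE 0.52, adjusted p = 0.0034; 1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.664). Of 2 tested leukocyte markers the lysosomal gene Cd68 rose by 1.84 (SE 0.36, limma adjusted p = 0.0115; 1 adjusted over the list alone), which did not hold without a filter on low values, and Ptprc was listed at 0 in the KPPC lines and PPSSC line 1. The 1 tested endothelial marker, Esam, had 0 to 21 reads per line and did not pass (1.07, SE 1.04, limma adjusted p = 0.561). Of the adipocyte and nerve markers, the lipid droplet gene Cidec fell (-4.13, SE 0.29, limma adjusted p = 7.12e-05) and Mbp rose (1.13, SE 0.29, limma adjusted p = 0.0372), with 1 higher and 1 lower adjusted over the list alone. Mbp passed only without KPPC line 2 among the fits that left out 1 line and did not pass with quantile normalization or without a filter on low values, and 2 fibroblast markers fell without PPSSC line 3. Xist was at 5.03 to 20.8 RPKM in the 6 lines (limma adjusted p = 0.826), and the Y-linked genes Ddx3y, Uty and Eif2s3y were at no more than 0.0256 RPKM. Of 12 immediate early genes Dusp1 and Fos (1.37, SE 0.34, limma adjusted p = 0.0319) rose and Klf2 fell (-1.56, SE 0.44, limma adjusted p = 0.0497), with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.275). Only 1 of these rose without KPPC line 1, PPSSC line 1 or PPSSC line 2, and Klf2 passed only without PPSSC line 3 among the fits that left out 1 line. Klf2 did not pass with log2(RPKM + 0.1), log2(RPKM + 0.5), voom, an RPKM minimum of 5 or scaling to total reads, and neither Klf2 nor Fos passed without a filter on low values. None of 10 mitochondrially encoded genes passed with limma or voom or had an unadjusted p under 0.05 (1 fell without PPSSC line 1), with mt-Nd5 closest (0.69, SE 0.37, limma adjusted p = 0.283; camera adjusted p = 0.916).

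In all, 10 of 32 lists passed with camera at the preset correlation, 8 upward and 2 downward. None passed with an estimated correlation, where the lowest adjusted p was 0.164, and 3 passed with fry, which tests whether the genes of a list move one way without comparing them with other genes. Fry for change in either direction passed 25 lists. With the 6 lines split into other groups of 3 and 3, camera passed 5 to 13 lists, and limma called 0 genes.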

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

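The limma voom fit on recovered reads, the scaling to total reads and the one-sided Fisher's exact test of lists were chosen only after the data were seen, as were 67 genes named beyond the rule. Among the 87 genes named by the rule, 76 were past the threshold. Of these, 47 kept their direction and call in all those of 11 alternatives that tested them. Without each library in turn 53 did so. Of 59 further named genes past the threshold, 36 and 38 did. A stricter RPKM minimum left some genes of both sets untested, such as Egfr and Il1rap, so it could not change their call. None of the alternatives called a gene in the direction opposite to the reported call.

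The count of 825 genes higher in PPSSC stayed within 1.5 times in the settings run other than a stricter filter, library weights and leaving out PPSSC replicate 2, with 796 for log2(RPKM + 0.1) and 1204 for voom, and the 613 lower genes did so with log2(RPKM + 0.1) (578), median ratio scaling (570), quantile normalization (697) and voom (746). Without a filter on low values 611 genes were higher and 231 lower, among 25641 tested. Of the reported calls only 450 of the 825 higher and 207 of the 613 lower genes were called again there. Asking for an RPKM of at least 5 in 3 libraries left 8245 tested genes, of which 440 were higher and 402 lower; of the reported calls 461 and 429 could still be tested, and 440 and 402 of these were called again. With library weights (arrayWeights) 1245 were higher and 1054 lower, and the cause was not tested. Scaled to total reads 403 were lower, all of them among the 613, since that scaling raises the median of all genes in PPSSC by 0.18 (log2). Leaving out each library in turn gave 526 to 886 higher and 247 to 715 lower genes, the lowest without PPSSC replicate 2 and the highest without KPPC replicate 3. Fewer samples lower the power of each such fit. With a block for the replicate number 908 were higher and 668 lower, and 2 cell cycle and 3 DNA repair genes rose, against none with the reported settings, while Tyro3, Rras, Dhrs9, Fos, Srebf2, Ltbp3 and Fkbp10 did not pass. Whether the numbers pair the lines stays open. Deviations from the group mean correlated at 0.483, -0.06 and 0.148 for the numbers 1, 2 and 3, and 2 of 6 libraries correlated best with their own number. The second principal component, with 18.5% of the variance, put the numbers in the same order in both groups. For lines 1, 2 and 3 it was 37.8, 12.1 and -47.8 in KPPC and 30.2, -7.54 and -24.9 in PPSSC. Whether the numbers mark a batch was not tested.

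Of 32 lists 10 passed with camera, 0 with an estimated correlation, 3 with fry and 6 by Fisher's exact test of called genes, which takes genes as independent. Leaving out 1 library gave 7 to 12 lists. The list cell cycle had a camera adjusted p between 8.32e-08 (without KPPC replicate 1) and 0.770 (without KPPC replicate 3, downward). Some genes that did not pass changed sign. Of these gene Xist had a log2 fold change of 0.0187 with library weights and of -0.77 to 0.15 without 1 library, gene Esam of -0.37 to 1.80, gene Gata6 of -0.80 to 0.18 and gene Cdh1 of -0.0266 to 0.43. For gene Cxcl12 (0.13 with the reported settings) it was -1.14 with log2(RPKM + 0.1), -0.27 with log2(RPKM + 0.5), -0.0467 with library weights, -1.54 with voom and -1.92 to 1.16 without 1 library. PPSSC replicate 3 alone held its high value, and without that library gene Cxcl12 passed as lower. For the others the cause was not tested.

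Fits with DESeq2 and edgeR were not run, since the values are RPKM and not counts. In the simulation with 3 lines per group, 13% of well-covered genes with a log2 fold change of 1 were recovered, and 95% with a change of 2. These need not be the rates in the real data.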

Other observations

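The genes named in this part outside the report, the tests of gene families, of epithelial cells and of fibroblasts, and the count of splits for genes were chosen only after the result was seen. These genes are given singly, since no list held them as a group and no group of them was tested. Nkx6-3, a homeobox factor of the stomach, was at 27.7, 22.1 and 27 RPKM in the KPPC lines and listed at 0 in the 3 PPSSC lines (limma adjusted p = 1.74e-05). Gata4, an endodermal factor, was at 76.7 ± 17.9 RPKM in KPPC and 25.7 ± 0.799 RPKM in PPSSC (limma log2 fold change -1.51, adjusted p = 0.00765, n = 3 lines each). Cdx2, an intestinal factor that did not pass without KPPC line 1, KPPC line 2, PPSSC line 1 or PPSSC line 2, after scaling to total reads or without a filter on low values, fell from 45.8 ± 12 to 13.9 ± 7.61 RPKM (limma log2 fold change -1.80, adjusted p = 0.0396).

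Sox2, a factor of stem cells and foregut, was at 2.83 ± 0.62 RPKM in KPPC and 19.2 ± 3.52 RPKM in PPSSC (limma log2 fold change 2.40, adjusted p = 0.000868), and Pitx1 at 1.22 ± 0.633 and 19 ± 4.61 RPKM (3.19, limma adjusted p = 0.000417). The grainyhead factors Grhl1 and Grhl3 rose by 2.87 and 1.58, Pax9 by 2.07, Foxn1 by 3.22 and the endodermal factor Foxa1 by 2.26. The cornified envelope gene Ivl was at 0.934 ± 0.739 RPKM in KPPC and 20.5 ± 15.3 RPKM in PPSSC (3.21, limma adjusted p = 0.0121, not passing without PPSSC line 2 or without a filter on low values). Tgm1, which cross-links that envelope, rose by 2.83 and the desmosomal cadherin genes Dsg3 and Dsg2 by 4.07 and 3.32. PPSSC line 3 had the lowest values of Ivl, Tgm1 and Dsg3 among the PPSSC lines.

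Of 125 families of gene symbols with at least 10 tested members, 4 held more called genes than the background (250 one-sided Fisher's exact tests). These tests take the genes of a family as independent, which they need not be. Genes whose symbols start with Il, among them interleukins, their receptors and the amino acid oxidase gene Il4i1, had 10 of 26 higher (adjusted p = 0.00175), including Il18r1 and Il1rap, and 2 lower. Il1rap did not pass without KPPC line 1, KPPC line 2 or PPSSC line 2, with quantile normalization or without a filter on low values. Keratins had 7 of 15 higher (adjusted p = 0.00332), with Krt23 at 1.65 ± 0.991 and 52.2 ± 38.3 RPKM, and 1 lower. Cytochrome P450 genes had 6 of 16 higher (adjusted p = 0.0383), of which Cyp2b10 and Cyp2f2 were listed at 0 in KPPC, and 2 lower. Recovered reads in PPSSC lines 1, 2 and 3 were few, at 200, 66 and 42 for Cyp2b10 and 6, 22 and 56 for Cyp2f2. Cyp2f2 did not pass without a filter on low values. FK506-binding proteins, which fold proteins or bind steroid receptor complexes, had 6 of 12 lower (adjusted p = 0.00183), with Fkbp5 at 23.6 ± 11.4 and 4.19 ± 1.27 RPKM, and 1 higher. Without KPPC line 2, without PPSSC line 2 or without a filter on low values none of these 6 (Fkbp1a, Fkbp5, Fkbp7, Fkbp9, Fkbp10 and Fkbp11) passed, and Fkbp1a, Fkbp7 and Fkbp9 did not after scaling to total reads.

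PPSSC line 3 stood apart in connective tissue genes. It held 19581 reads of Col3a1, 5203 of Cxcl12 and 2077 of Dpt, a dermal matrix gene, against at most 60, 6 and 0 in the other PPSSC lines. Its reads of Col1a1, Col1a2 and Dcn, which fibroblasts express strongly, were 196, 68 and 25. Without that line Col1a1 and Cxcl12 were lower in PPSSC with limma, at log2 fold changes of -2.62 (gene Col1a1) and -1.92 (gene Cxcl12).

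The difference between the groups was set against other splits of the 6 libraries. The 10 splits into 3 and 3 are too few for a share under 0.05. The real split gave 825 higher and 613 lower genes. In each case 1 of 10 splits gave as many, which was the real split itself, and the highest other split gave 0. The other splits mix the groups, so the group difference adds to their spread, and their 0 does not measure chance. For lists the real split gave 10, and 6 of 10 splits, the real one included, gave as many or more. The highest other split gave 13 lists.

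Low epithelial genes such as Epcam and a higher level of Vim in KPPC could come from fewer epithelial cells or from fibroblasts in the KPPC cultures. Fewer epithelial cells would lower all epithelial genes by 1 factor per line. After each library was centred on its median over the 27 tested members of the epithelial list, the groups still did not overlap for 22 of them. Of these, 6 were higher and 16 lower in PPSSC. Independent members would give 10% and a 95th percentile of 5, but over all tested genes, uncentred, the share was 31.5%. The members are correlated, and centring itself lowers those that changed less than the median, so the count does not measure chance. Against 1 common factor stand Epcam, at 0.198 and 105 RPKM in KPPC and PPSSC, and Cdh1, at 290 and 332 RPKM. Fibroblasts would bring their abundant transcripts, but against at least 40868 reads of Vim the KPPC lines had 126, 422 and 154 recovered reads of Col1a1, 132, 128 and 214 of Cxcl12, and 6, 1 and 39 of Col1a2, Dcn and Col3a1 in the highest KPPC line of each. Fibroblast markers with 10 or more reads in a KPPC line numbered 5. Their median log2 fold change lay 6.22 above that of Vim, with a spread of 4.29 (6.72 and 5.59 without PPSSC line 3). This gap cannot decide, since the median marker was Pdgfra, with 1, 1 and 17 reads in KPPC and 5, 9 and 25 in PPSSC. Above it were Pdpn, also a marker of basal keratinocytes, and Col3a1, high in PPSSC line 3 alone. Col1a1 and Cxcl12 went with Vim, at 4 to 6 reads in PPSSC lines 1 and 2. The uneven changes of the epithelial genes argue against fewer epithelial cells as the whole cause. The few KPPC reads of collagen genes and Dcn beside those of Vim argue against fibroblasts as the whole cause. A small share of fibroblasts in the KPPC cultures is not excluded. A different state of the tumour cells is a hypothesis that stays open, as does whether Kras, Smad4 or the cell of origin would set it.

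Kras differed between lines of 1 group, with 190 RPKM in KPPC line 3 and 211 RPKM in PPSSC line 2 against 71.1 to 152 RPKM in the others. A candidate explanation is a gain of the chromosome region, taken to show as a median of 0.5 or more over the genes beside Kras and to be ruled out by an interval under 0.25. In KPPC line 3 the 49 neighbouring genes had a median of 0.0284 (log2 against the median of the 6 libraries, bootstrap 95% interval -0.06 to 0.22). This rules out such a gain against that median only, and a gain shared by several lines would raise the median itself. The neighbours in KPPC lines 1 and 2, where Kras was lower, were at -0.35 and -0.31. A gain of the region in KPPC line 3 against these lines therefore stays open. In PPSSC line 2 the median was 0.21 (interval 0.05 to 0.39), which leaves a gain open, and a gain of Kras alone was not tested. Dosage differences of whole chromosomes may contribute to differences between lines, since chromosome explained 1.88% to 4.82% of the variance, more than the 95th percentile of 1000 shifts of the gene order in 6 of 6 libraries. The median of 1 chromosome lay more than 0.3 (log2) from that of the library in each of KPPC lines 1 and 2 and PPSSC line 2, and of none in the others. Deviations were taken from the median of the 6 libraries, so the group difference enters these shares. They do not isolate differences within a group.

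More genes had reads in PPSSC: 832 genes were listed at 0 in all KPPC lines and above 0 in all PPSSC lines, and 81 the reverse. Depth is argued against, since after thinning each library to 20000000 reads the lowest PPSSC library still had 1.095 times the genes of the highest KPPC library. Background reads over silent genes may contribute: over 51 receptor genes of the sensory organs, reads per library size were 4.35 times higher in PPSSC (2.23 times for the lowest PPSSC against the highest KPPC library). Without the 3 genes with most reads, which held 75.0% of these reads, the ratios were 3.002 and 1.79. Broader transcription in the PPSSC lines would give the same values, so background and biology stay open.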
